A study of Mus musculus with 24 samples.

How the data were processed

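Total liver RNA of 24 biological replicates, 4 females and 4 males for each of WT, G62C and R341H human keratin 8, had been labelled with biotin and hybridised to Affymetrix mouse arrays. The livers came from untreated mice under basal conditions. The authors processed the arrays with RMA (robust multi-array average), which corrects background, normalises probes by quantiles and summarises each probe set; no version or filter was given. The deposited values are on the log2 scale, with 1 value per probe set and array and none missing. No scan date or batch was given, so differences between hybridization days could not be examined. Array medians lay between 5.036 and 5.116 log2 units, and the number of arrays limits the precision. The 3' minus 5' differences of 4 control transcripts were compared between each variant and WT within each sex by exact two-sided permutation tests, adjusted over 16 tests, which were chosen after the values had been seen.

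The table held 45101 probe sets, from which 64 control probe sets were left out. The platform table gave 1 gene for 34945 of the 45037 probe sets tested, several genes for 932 and none for 9160. Symbols were checked through gene numbers against RefSeq genes of assembly GRCm38.p6, which was used only for names, chromosomes and the order of neighbouring genes; 34741 probe sets were found and 0 symbols changed. Each of the 18193 genes is described by the probe set with the highest mean over all arrays.

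Differences were tested with limma 3.58.1 in R 4.3.3, in a model with 1 mean per group and variances moderated over all probe sets. The contrasts were each variant against WT and G62C against R341H averaged over sexes, each variant against WT within each sex, the difference between those within-sex contrasts (interaction), and females against males averaged over genotypes. P-values were adjusted by Benjamini and Hochberg over all 45037 probe sets in each contrast, with 0.05 as the threshold; 2252 probe sets would be under an unadjusted 0.05 by chance. In simulated data with 67 probe sets changed by 0.5 on the log2 scale, 91% were recovered for G62C against WT and 76.1% for G62C against WT in females. The simulated noise was normal and independent between probe sets and arrays, so these shares do not bound the differences that failed to pass.

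In each contrast, 40 lists of genes covering hepatic pathways and markers of liver cell types, fixed before the data were examined, were tested with camera in limma, with a preset correlation between members of 0.01, and again with an estimated correlation. The adjusted p is over the 40 lists. Beside the count over all genes, members were counted when adjusted over the list alone. Another test, fry, asks whether the members of a list move, on balance, one way, without a comparison with other genes. Over all 40 lists fry called 1 for G62C, 2 for R341H and 11 for G62C against R341H. It called 5 and 0 in G62C females and males, and 2 and 1 in R341H females and males. For the interactions of G62C and R341H it called 2 and 0, and between the sexes 16. Of the calls made with the preset correlation over all contrasts, 33 also passed fry and 89 did not. Of the lists called with the preset correlation, 15 for G62C, 12 for R341H and 14 for G62C against R341H, the estimated correlation kept 1, 0 and 1. It kept 2 of 18 in G62C females, 0 of 10 in G62C males, 0 of 10 in R341H females, 1 of 8 in R341H males, 2 of 14 and 0 of 12 in the interactions, and 3 of 9 between the sexes.

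Genes to be named were chosen by a rule set before the data were examined. It took up to 12 rises and 12 falls with the largest log2 difference and the same sign in both sexes for genotype contrasts (in all genotypes for the sex contrast), up to 5 each way within a sex, and up to 6 with the smallest p in an interaction. It added Krt8, Krt18 and, from each list called or with a member past the threshold, up to 4 members with the smallest p; the text names a part of these. The number of G62C or R341H arrays on the called side of the WT mean of the same sex (of R341H for G62C against R341H) is given for leading genes. The X-linked neighbours Tlr8, Tlr7, Prps2 and Amelx and the value of Xist per array were chosen after their values were seen.

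Agreement between sexes and between variants was measured as the Pearson correlation of differences across 18193 genes. Chance for the sexes came from 100 shufflings of genotype labels within sex. For the variants it came from 100 simulations of unchanged groups sharing the WT arrays, built from residuals, and from dividing the WT arrays in 36 ways. Each count was also compared with up to 100 other splits of the same arrays. Alternatives were a filter on probe sets under the median brightness of 5.07, 1 probe set per gene, new quantile normalization, median centring, an intensity trend with robust variances, array weights, the replicate number as a block, fits to the compared groups alone, a fold threshold of 1.5, an additive model and each array left out in turn. Added after the data were seen were fits without R341H female replicate 3 and G62C male replicate 2, which had unusual Xist values, and counts without genes of chromosomes 9 and X. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.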

Results

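Total liver RNA was measured on 24 Affymetrix arrays, 1 per biological replicate, from untreated mice of FVB/N background that overexpressed human keratin 8 (K8), an intermediate filament protein of hepatocytes. The transgene carried the wild-type sequence (WT) or the variant G62C or R341H, both known from people with liver disease. Each genotype was represented by 8 arrays, 4 from females and 4 from males, which gave 6 groups of 4 arrays. No mice without a transgene were part of the series, so each variant was compared with overexpressed WT K8. Of the 45037 probe sets tested, 34945 belonged to 1 gene each, and they covered 18193 genes. The number of arrays limits the precision of every difference. Differences are log2 values ± standard error, with n = 8 arrays per genotype for averages over both sexes and n = 4 per group within a sex, and a gene rose or fell where its adjusted p was under 0.05.

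Sex separated the arrays more than genotype did. The first principal component held 30.2% of the variance, with all 12 female arrays between -25.58 and -15.67 and all 12 male arrays between 16.67 and 28.17. The second component held 9.37%, and the arrays of each genotype spread along it. The 4 G62C females lay between 7.621 and 15.34 on it and the 4 R341H females between -20.55 and -6.792. WT females overlapped both, and the male groups overlapped each other. Correlations between arrays of the same group lay between 0.9918 and 0.9965 over 36 pairs. The 3' minus 5' difference of the Gapdh control probe sets, a sign of RNA quality, was -0.330 ± 0.0125 (SD, n = 4) in WT females, -0.277 ± 0.0368 in G62C females and -0.281 ± 0.04 in R341H females. In males it was -0.266 in WT, -0.232 in G62C and -0.227 in R341H. All 4 G62C females lay above all 4 WT females (exact two-sided permutation p = 0.0286, the smallest this design allows, and adjusted p = 0.457 over 16 such tests of 4 control transcripts). The other 3 Gapdh differences from WT were also above 0, with exact permutation p = 0.0571, 0.171 and 0.143 for R341H females, G62C males and R341H males. The Y-linked transcript Eif2s3y was between 7.99 and 8.56 log2 units in the 12 males, and at most 3.27 in the 12 females. Xist, the RNA that coats the inactive X chromosome, was between 9.17 and 9.91 in 11 females. R341H female replicate 3 had a Xist value of 4.99, within the male range of 4.69 to 5.93, while its Eif2s3y value of 3.27 was far from the male range.

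**Figure D1:**
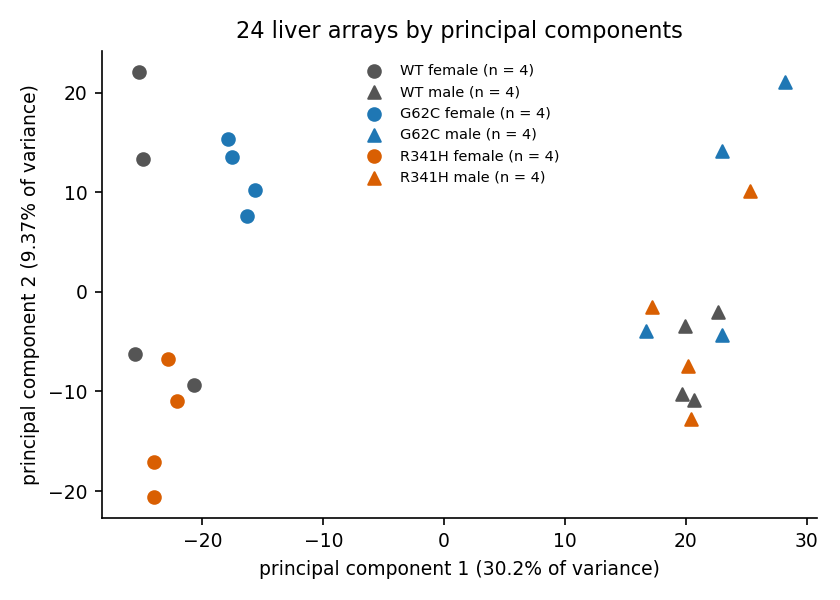
Each point is 1 array placed by its first and second principal component over all probe sets tested, coloured by genotype, with circles for females and triangles for males. The first component, with 30.2% of the variance, has females at or under -15.67 and males at or over 16.67.

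The arrays carry probe sets designed for the transcripts of the mouse's own keratins. Krt8 differed from WT by 0.07 ± 0.09 in G62C (adjusted p = 0.897) and by 0.20 ± 0.09 in R341H (adjusted p = 0.382). Krt18, the partner of keratin 8 in hepatocyte filaments, differed by -0.12 ± 0.08 in G62C (adjusted p = 0.719) and by -0.34 ± 0.08 in R341H (adjusted p = 0.053). Neither gene passed the test in either variant, and none of the 19 genes listed for keratins and the epithelial cytoskeleton passed it either. The amount of the human transgene RNA is not known from these mouse probe sets. Whether that RNA added to the Krt8 signal was not tested.

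The comparison of G62C with WT asked what the variant changes in the unchallenged liver. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.28 ± 0.23 (adjusted p = 0.0258) and was lower than the WT mean of the same sex in 8 of 8 G62C arrays. Sc5d, an enzyme of the late steps of cholesterol synthesis, fell by 0.94 ± 0.12 (adjusted p = 0.000628, lower in 8 of 8 arrays), although its 2 other bright probe sets differed by only -0.24 and -0.08. Nox4, an NADPH oxidase that makes hydrogen peroxide, rose by 0.89 ± 0.16 (adjusted p = 0.0284, higher in 7 of 8 arrays). Its rise was 1.71 in females, while G62C males lay at 9.181 to 9.943 around the 9.456 to 9.665 of WT males. The lipid droplet protein gene Plin5 rose by 0.55 ± 0.11 (adjusted p = 0.0387, higher in 8 of 8 arrays), and Cyp4a12a, a fatty acid hydroxylase of male liver, rose by 0.64 ± 0.09 (adjusted p = 0.00174, higher in 7 of 8 arrays). The female difference of Cyp4a12a lay 1.24 above the male one, so its average rise came mostly from females.

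In all, 39 probe sets passed in this comparison, 21 higher and 18 lower in G62C, where 3971 had an unadjusted p under 0.05 and chance gives 2252. Described by their brightest probe sets, with p adjusted over all probe sets, 10 genes rose and 11 fell. Rcn2, a calcium-binding protein of the endoplasmic reticulum, fell the most (-1.29 ± 0.15, adjusted p = 0.000158), followed after Cyp7a1 by Nxpe2 (-1.05 ± 0.14, adjusted p = 0.000628). Onecut1, a hepatocyte transcription factor, fell by 0.65 ± 0.13 (adjusted p = 0.0386), with -0.23 for its other bright probe set. Gamt, which makes creatine, and the cytoskeletal actin gene Actg1 fell by 0.54 and 0.53. The interferon-induced genes Ube2l6 and Rtp4 and the immunoproteasome subunit Psmb10 fell by 0.38, 0.35 and 0.29, and Fam219b fell by 0.27. Among the genes that rose were the trehalase gene Treh (0.58), Tanc2 (0.53), the xanthine dehydrogenase gene Xdh (0.48), Zc3h12c (0.40), Gdpd1 (0.37), Shld2 (0.37) and the ciliary transport gene Ift46 (0.22). Sc5d, Treh, Ift46, Nxpe2, Zc3h12c, Rcn2, Fam219b and Onecut1, 8 of these 21 genes, lie on chromosome 9. Dimmer probe sets of Rcn2 (0.021) and Tanc2 (-0.010) lay on the other side of 0 and did not pass. Cyp4a12a, Rcn2, Nxpe2 and Sc5d were the 4 of 21 that passed whichever array was left out. The number of probe sets that passed ranged from 9 without WT male replicate 2 to 63 without WT female replicate 1.

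Interferon-stimulated genes were lower in G62C as a group: 28 of 30 measured members were below WT, with a median of -0.18. Their test against all other genes gave an adjusted p of 1.95e-12, and adjusted p = 0.0178 with an estimated correlation between members. Over all genes 1 member, Rtp4, fell and 29 did not pass; 8 members fell when adjusted over the list alone. Within the sexes, 28 of 30 were below WT in females and 15 of 30 in males (median 0.00203, adjusted p = 0.867 in males). Kupffer cell and macrophage markers were lower alongside them, in 19 of 20 members (median -0.203, adjusted p = 5.18e-11). That call was lost with an estimated correlation (adjusted p = 0.163), none of the 20 markers passed over all genes, and 12 fell when adjusted over the list alone. Mpeg1, a macrophage pore protein, differed by -0.28 ± 0.06 (adjusted p = 0.0731). T and NK cell markers were also below WT in 14 of 18 members (adjusted p = 0.00737, and adjusted p = 0.163 with an estimated correlation).

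Genes of cholesterol biosynthesis were below WT in 20 of 21 members in G62C, with a median of -0.376 (adjusted p = 1.68e-13). The call was lost with an estimated correlation (adjusted p = 0.24). Over all genes Sc5d fell and 20 did not pass, while 12 members fell when adjusted over the list alone. In females 16 of 21 were below WT (adjusted p = 0.0892) and in males 20 of 21. Msmo1, a sterol demethylation enzyme, differed by -1.17 ± 0.33 (adjusted p = 0.211). PPAR alpha targets and fatty acid oxidation genes lay above WT in 28 of 33 members (adjusted p = 2.64e-06, and adjusted p = 0.41 with an estimated correlation), but in 16 of 33 in females (adjusted p = 0.903). Heat shock and keratin aggregate proteins lay above WT in 12 of 15 members (adjusted p = 4.8e-05, and adjusted p = 0.304 with an estimated correlation), with 12 of 15 in females (adjusted p = 2.5e-05, and adjusted p = 0.195 with an estimated correlation) and 11 of 15 in males (adjusted p = 0.264). The chaperone gene Hspa1a differed by 1.13 ± 0.29 (adjusted p = 0.164), and G62C male replicate 1 was at 8.78 against 6.34 to 6.45 in the other 3 G62C males. Proteasome subunits were above WT in 26 of 30 members (adjusted p = 1.06e-05) and ribosomal proteins below it in 25 of 27 (adjusted p = 2.07e-07). Both lost the call with an estimated correlation, with an adjusted p of 0.41 each.

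The comparison of R341H with WT asked the same for the second variant. Nnmt, which methylates nicotinamide, fell by 2.11 ± 0.27 (adjusted p = 0.000189), and Cyp17a1, a steroid hydroxylase, fell by 1.27 ± 0.16 (adjusted p = 0.000159), both lower in 8 of 8 R341H arrays than the WT mean of the same sex. The fall of Cyp17a1 was mostly in females, at 7.617 to 8.783 in R341H against 10.05 to 11.21 in WT. In males Cyp17a1 lay at 6.419 to 6.932 in R341H and 6.818 to 7.134 in WT. Nox4 rose by 1.08 ± 0.16 (adjusted p = 0.00113, higher in 8 of 8 arrays). Its rise was 2.03 in females, while R341H males lay at 9.594 to 9.88 against 9.456 to 9.665 in WT males. The interferon-inducible GTPases Gbp8 and Gbp6 rose by 0.83 ± 0.17 (adjusted p = 0.0155) and 0.79 ± 0.10 (adjusted p = 0.000159), each in 8 of 8 arrays. Cd163, a scavenger receptor of resident macrophages, fell by 0.58 ± 0.11 (adjusted p = 0.0137).

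In R341H 248 probe sets passed, 181 higher and 67 lower; 5656 had an unadjusted p under 0.05. Further rises were in the water channel gene Aqp8 (0.72), the vesicle transport gene Rab8b (0.63), the steroid dehydrogenase gene Hsd3b2 (0.62), the G protein subunit gene Gna14 (0.62), Arhgap6 (0.61), Rtn4 (0.56), Meiob (0.51), the activin subunit gene Inhbc (0.51) and the succinate receptor gene Sucnr1 (0.50). The X-linked Arhgap6 differed by 0.918 in males and by 0.3 in females (adjusted p = 0.389 in females). The test of that difference between sexes did not pass (adjusted p = 0.471). Rcn2 fell by 1.14 ± 0.15 (adjusted p = 0.000184) and Wsb1 by 1.06 ± 0.23 (adjusted p = 0.0334). Inca1 (-0.89), Onecut1 (-0.73), Syt11 (-0.62), Actg1 (-0.52), the DNA polymerase subunit gene Pole4 (-0.50), the arsenic methyltransferase gene As3mt (-0.49) and Nlrp12 (-0.49) also fell. Among liver enzymes and receptors, Cyp3a13 fell by 0.43, while Cyp2c23 rose by 0.42 and the asialoglycoprotein receptor gene Asgr2 by 0.42. Other probe sets of Rcn2 (0.072), Inca1 (0.051), Syt11 (0.0055 and 0.015) and Pole4 (0.00094) did not pass and lay on the other side of 0. Of the 37 genes named by rule that passed, 22 passed whichever array was left out. The count was 134 without R341H female replicate 3, the array without Xist, and ranged from 121 without WT male replicate 2 to 371 without WT female replicate 2; it was 432 with probe sets above the median brightness only. With arrays centred on their medians the share of higher probe sets was 62.6%, against 73% with the deposited scaling.

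Interferon-stimulated genes were above WT in 26 of 30 members in R341H, with a median of 0.16 (adjusted p = 1.23e-08, and adjusted p = 0.0969 with an estimated correlation). Over all genes 5 members rose, Gbp6, Psmb8 (0.31), Gbp3 (0.38), Igtp (0.33) and Rtp4 (0.28), and 25 did not pass; 10 rose when adjusted over the list alone. In females 18 of 30 were above WT (median 0.0224, adjusted p = 0.16) and in males 27 of 30. The 8 measured genes of MHC class II antigen presentation were all above WT (median 0.226, adjusted p = 0.000183, and adjusted p = 0.418 with an estimated correlation). Cd74, the invariant chain, rose by 0.44 ± 0.10 (adjusted p = 0.0397), 7 did not pass, and 4 of the 8 rose when adjusted over the list alone. Kupffer cell and macrophage markers did not differ as a group (13 of 20 above WT, adjusted p = 0.541), and Cd163 was the member that passed.

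Genes of the urea cycle and amino acid metabolism were below WT in 21 of 26 members in R341H (median -0.132, adjusted p = 3.05e-08), a call lost with an estimated correlation (adjusted p = 0.345). Aass, which degrades lysine, fell by 0.26 and Hal, which degrades histidine, by 0.40; 24 members did not pass over all genes, and 13 fell when adjusted over the list alone. Cholesterol biosynthesis genes were above WT in 19 of 21 members (median 0.323, adjusted p = 1.13e-05, and adjusted p = 0.575 with an estimated correlation). None of them passed over all genes; adjusted over the list alone, 8 rose and 2 fell. In females 19 of 21 were above WT, while in males 16 of 21 were below it and the list did not pass (median -0.155, adjusted p = 0.149). The test of the difference between the sexes gave an adjusted p of 7.59e-15, and adjusted p = 0.237 with an estimated correlation. Hmgcs1, an early enzyme of the pathway, differed by 0.60 ± 0.15 (adjusted p = 0.0639). Proteasome subunits were below WT in 28 of 30 members (adjusted p = 1.01e-08) and ribosomal proteins in 26 of 27 (adjusted p = 3.68e-10). Both calls were lost with an estimated correlation, where the adjusted p was 0.418 for the proteasome and 0.509 for the ribosome.

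**Figure D2:**
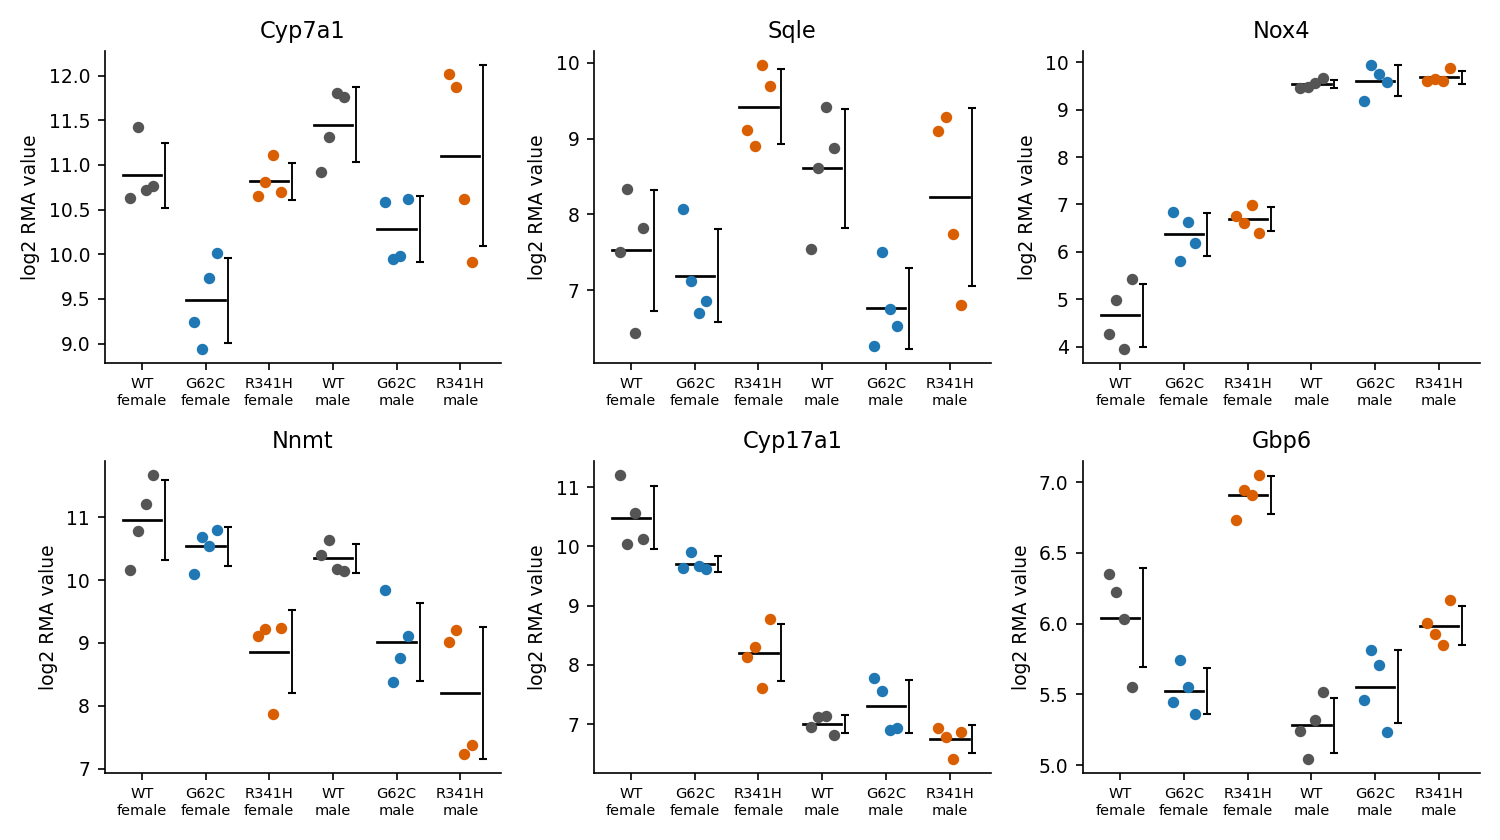
Each panel shows 1 gene's log2 value in the 24 arrays by group, with a line at each group's mean of 4 arrays and a bar for the standard deviation. Cyp7a1 averaged 1.28 log2 units less in G62C than in WT, and Nnmt 2.11 less in R341H.

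The comparison of G62C with R341H asked how the variants differ from each other; WT arrays entered it only through the pooled variances. Cholesterol synthesis enzymes were lower in G62C than in R341H: Sqle, Msmo1, Idi1 and Fdps fell by 1.85 ± 0.33, 1.80 ± 0.33, 1.72 ± 0.29 and 1.66 ± 0.28, each lower in 8 of 8 arrays (adjusted p = 0.00205, 0.00254, 0.00167 and 0.00141). Within R341H males Sqle spread widely, at 9.097 and 9.282 in replicates 1 and 2 and 7.741 and 6.812 in replicates 3 and 4. Interferon-stimulated genes were lower as well, with Gbp8 at -1.15 ± 0.17 (adjusted p = 0.000355), Gbp6 at -0.91 ± 0.10 (adjusted p = 1.8e-05) and Rtp4 at -0.62 ± 0.06 (adjusted p = 9.74e-06). Plin5 was higher by 0.95 ± 0.11 (adjusted p = 3.22e-05), as was Nnmt by 1.24 ± 0.27 (adjusted p = 0.0118). Srebf1, a transcription factor of lipid synthesis, fell by 1.08 ± 0.16 (adjusted p = 0.000508, lower in 7 of 8 arrays), and Insig2, which holds back sterol synthesis, rose by 0.85 ± 0.11 (adjusted p = 0.000204).

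Between the variants 1045 probe sets passed, 406 higher and 639 lower in G62C. Among the rises were Fam107a (1.76), the drug-metabolising enzyme gene Cyp2b10 (1.60), the fasting-induced Igfbp1 (1.22), the matricellular protein gene Ccn2 (1.14), Cyp17a1 (1.02), the tubulin gene Tubb2a (0.95), the aminotransferase gene Got1 (0.92), Nlrp12 (0.79) and the mitochondrial protease subunit gene Clpx (0.75). Among the falls were the thyroxine carrier gene Serpina7 (-1.32), Nsdhl (-1.20), Cyp51 (-1.12), Insig1 (-1.08), the cell cycle kinase gene Wee1 (-1.08), Cyp7a1 (-1.08), Gna14 (-0.68), Rtn4 (-0.59) and the asialoglycoprotein receptor gene Asgr2 (-0.40). Another probe set of Rtn4 (0.031) did not pass. Of the 86 genes named by rule that passed, 61 passed whichever array was left out. The count ranged from 675 without G62C male replicate 1 to 1189 without R341H male replicate 4, and it was 695 without G62C female replicate 4.

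All 30 interferon-stimulated genes were lower in G62C than in R341H (median -0.319, adjusted p = 2.87e-26), a call that held with an estimated correlation (adjusted p = 0.000242). Of these 14 fell and 16 did not pass over all genes, and 23 fell when adjusted over the list alone, among them Psmb8 (-0.42) and Igtp (-0.52). All 8 MHC class II genes were lower (adjusted p = 2.61e-08, and adjusted p = 0.0525 with an estimated correlation). H2-Aa (-0.79), H2-Ab1 (-0.75), Cd74 (-0.57) and H2-DMa (-0.53) were among the 5 that fell, with 3 not passing and the same count of 5 adjusted over the list alone. Markers of other cell types moved with these groups. Of 20 Kupffer cell and macrophage markers 6 fell, among them Adgre1 (-0.26), Cd5l (-0.38) and Mpeg1 (-0.25), while Cd163 rose by 0.46 (list adjusted p = 1.55e-09, and adjusted p = 0.106 with an estimated correlation). Of 18 T and NK cell markers 4 fell, Cd52 (-0.46), Gzma (-0.27), Nkg7 (-0.29) and Cd3g (-0.24), and 14 did not pass (list adjusted p = 0.000315, and adjusted p = 0.0525 with an estimated correlation). Adjusted over the list alone, 13 macrophage markers fell and 1 rose, and 7 T and NK cell markers fell.

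Of 21 cholesterol biosynthesis genes 15 fell in G62C against R341H and 6 did not pass (median -0.661, list adjusted p = 1.73e-22), with 19 lower and 1 higher when adjusted over the list alone. The list call was lost with an estimated correlation (adjusted p = 0.0588). Fdft1 (-1.02, and 0.085 for another probe set that did not pass) and Hmgcs1 (-0.94) were among them. In the opposite direction, 12 of 26 urea cycle and amino acid genes rose and 14 did not pass (list adjusted p = 1.51e-12, and adjusted p = 0.0525 with an estimated correlation), with 14 rising when adjusted over the list alone. Aass (0.48), Mat1a (0.31), Bhmt (0.30) and Tdo2 (0.23) were the members with the smallest p. Of 30 proteasome subunits 12 rose and 18 did not pass (list adjusted p = 5.73e-19, and adjusted p = 0.0769 with an estimated correlation); 21 rose when adjusted over the list alone, among them Psmd4 (0.41) and Psmc1 (0.29). Of 19 circadian clock genes 6 fell, among them Wee1, Tef (-0.52) and Dbp (-1.03), Clock rose by 0.64, and 12 did not pass (list adjusted p = 8.76e-05, and adjusted p = 0.111 with an estimated correlation). Adjusted over the list alone, 9 clock genes fell and 2 rose. Whether the time of day or feeding differed between the groups was not tested.

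**Figure D3:**
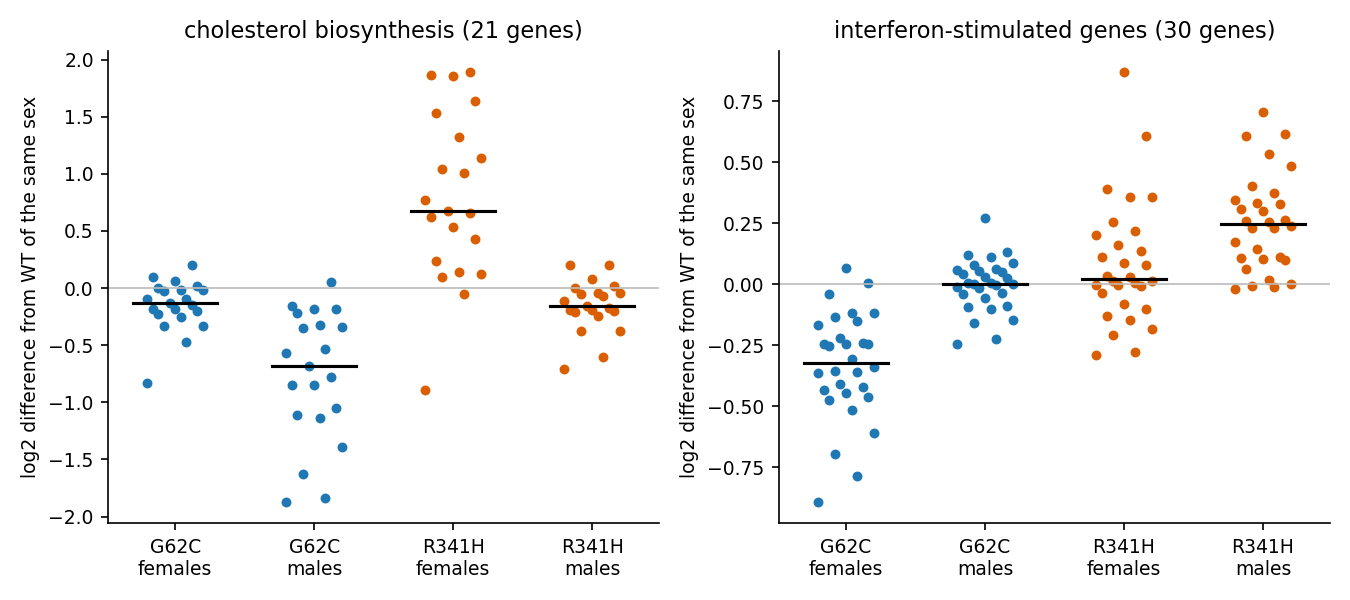
Each point is 1 gene of a list, placed at its log2 difference from WT within a sex, for 21 cholesterol biosynthesis genes and 30 interferon-stimulated genes, with a bar at the list's median. The median of the cholesterol genes was -0.685 in G62C males and 0.672 in R341H females, and that of the interferon-stimulated genes was -0.321 in G62C females and 0.247 in R341H males.

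Within the sexes, the question was whether females and males respond alike. In G62C females, whose 4 Gapdh 3' minus 5' differences all lay above those of WT females, 92 probe sets passed, 51 higher and 41 lower. Nox4 rose by 1.71 ± 0.23 (adjusted p = 0.000957), Cyp4a12a by 1.26 ± 0.13 (adjusted p = 1.9e-05) and Cyp1a1, an enzyme induced by the aryl hydrocarbon receptor, by 1.12 ± 0.15 (adjusted p = 0.000957). The chaperone gene Hspa1b rose by 1.55 and the complement gene C8a by 0.86, while Cyp3a44 (-1.46), the splicing factor gene Srsf5 (-1.30), Rcn2 (-1.23), the neutrophil gene S100a8 (-1.14) and Nrep (-1.06) fell. Of 30 interferon-stimulated genes Rtp4 (-0.69) and Irgm2 (-0.89) fell (0.090 for a dim probe set of Rtp4 that did not pass), 28 did not pass, and 20 fell when adjusted over the list alone; the list's adjusted p was 3.54e-20, and adjusted p = 0.00121 with an estimated correlation. Kupffer cell and macrophage markers were below WT in 18 of 20 members in these females (adjusted p = 2.8e-12, and adjusted p = 0.1 with an estimated correlation). Genes of acetaminophen metabolism were above WT in 13 of 15 members (adjusted p = 9.4e-07, and adjusted p = 0.0403 with an estimated correlation). Gstp1, a glutathione transferase, rose by 0.52 and Cyp3a11 by 0.27, 13 members did not pass, and 6 rose when adjusted over the list alone. Lists that share members with it were also above WT in these females: NRF2 targets in 26 of 33 members, pericentral zonation genes in 18 of 22 and cytochrome P450 genes in 34 of 47 (adjusted p = 0.000508, 0.00177 and 0.00365). These 3 calls were lost with an estimated correlation (adjusted p = 0.195, 0.244 and 0.396).

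In G62C males 9 probe sets passed, 5 higher and 4 lower. Treh rose by 1.03 ± 0.16 (adjusted p = 0.0218) and Capn8 by 0.53 ± 0.09 (adjusted p = 0.0448). Rcn2 (-1.35), Nxpe2 (-1.09), Sc5d (-1.05) and Tmem14a (-0.75) fell, with 0.063 for the dim probe set of Rcn2. Cholesterol biosynthesis genes were below WT in 20 of 21 members (median -0.685, adjusted p = 6.95e-24, and adjusted p = 0.229 with an estimated correlation); Sc5d passed over all genes, and 15 fell when adjusted over the list alone. PPAR alpha targets were above WT in 31 of 33 members (adjusted p = 3.44e-14, and adjusted p = 0.312 with an estimated correlation). None of the 6 named genes passed whichever array was left out: the count was 0 without G62C male replicate 1, WT male replicate 1 or WT male replicate 3, where limma was the only tool run and 2574 probe sets had an unadjusted p under 0.05 with all arrays. Without genes of chromosomes 9 and X, 1 probe set passed in G62C males. Among females the count was 37 without G62C female replicate 3. Of the 18 genes named by rule that passed in G62C females, 7 passed whichever array was left out. The calls of Hspa1b, C8a and Cyp3a44 there were lost in 16, 17 and 14 of the 24 fits.

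In R341H females 295 probe sets passed, 202 higher and 93 lower. Nox4 rose by 2.03 ± 0.23 (adjusted p = 3.26e-05), and the sterol enzymes Idi1, Fdps and Cyp51 rose by 1.87, 1.86 and 1.53, as did the ephrin gene Efna1 by 1.33. Cyp17a1 fell by 2.28 ± 0.22 (adjusted p = 8.98e-06), Nnmt by 2.09, the acute phase gene Lcn2 by 2.07, the estrogen sulfotransferase gene Sult1e1 by 1.93 and Cyp3a44 by 1.84. Of 21 cholesterol biosynthesis genes 7 rose, 14 did not pass, and adjusted over the list alone 15 rose and 1 fell; the list's adjusted p was 5.33e-14, and adjusted p = 0.275 with an estimated correlation. A dim probe set of Fdps (-0.062) did not pass. Cyp8b1, an enzyme of bile acid synthesis, fell by 0.94 and Srebf1 rose by 1.02. The count rested on single arrays: it was 68 without R341H female replicate 3, the array without Xist, 32 without WT female replicate 3 and 537 without WT female replicate 2. Of the 26 genes named by rule that passed in R341H females, 4 passed whichever array was left out. Without R341H female replicate 3 the cholesterol list kept its direction with an adjusted p of 4.3e-11.

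In R341H males 31 probe sets passed, 26 higher and 5 lower. The X-linked genes Arhgap6, Hccs and Msl3 rose by 0.92 ± 0.14 (adjusted p = 0.00579), 0.88 ± 0.07 (adjusted p = 9.94e-08) and 0.85 ± 0.07 (adjusted p = 1.33e-07). Hccs attaches heme to cytochrome c, and Msl3 belongs to a histone acetyltransferase complex. Tsc22d1 (0.87) and Rtn4 (0.75) rose, and Nnmt (-2.13), Rcn2 (-1.29), Inca1 (-0.76) and the methyltransferase gene Setd4 (-0.67) fell. Other probe sets of Tsc22d1 (-0.0065), Rtn4 (-0.071 and -0.064), Rcn2 (0.058) and Inca1 (0.11) did not pass and lay on the other side of 0. Of 30 interferon-stimulated genes Rtp4 (0.53) and Gbp6 (0.71) rose, 28 did not pass, and 13 rose when adjusted over the list alone; the list's adjusted p was 8.09e-15, and adjusted p = 0.00735 with an estimated correlation. Ribosomal proteins were below WT in 27 of 27 members (adjusted p = 8.93e-18, and adjusted p = 0.47 with an estimated correlation). The count was 6 without WT male replicate 1, 7 without R341H male replicate 4 and 13 without genes of chromosomes 9 and X. Of the 11 genes named by rule that passed in R341H males, 3 passed whichever array was left out.

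The test of the difference between sexes itself gave 1 probe set for G62C and 11 for R341H. For G62C it was Cyp4a12a, with a female difference 1.24 ± 0.18 above the male one (adjusted p = 0.017), a call that was lost when each of 5 of the 24 arrays was left out. For R341H, Msl3 (-0.98 ± 0.10, adjusted p = 1.95e-05), Hccs (-0.83 ± 0.10, adjusted p = 0.000242), Cyp17a1 (-2.03 ± 0.32, adjusted p = 0.0115) and Cyp3a44 (-2.42 ± 0.44, adjusted p = 0.0373) had a lower difference in females than in males. Tmem14a (1.20 ± 0.19, adjusted p = 0.0142), Nox4 (1.89 ± 0.33, adjusted p = 0.0232) and Tmem107 (0.71 ± 0.13, adjusted p = 0.0324; -0.024 for a dimmer probe set) had a higher one. When each of the 24 arrays was left out, the call was lost 2 times for Tmem14a, 11 for Nox4, 12 for Tmem107 and 13 for Cyp3a44. Among the lists, interferon-stimulated genes moved lower in G62C females than in G62C males in 28 of 30 members (median -0.321, adjusted p = 5.62e-13, and adjusted p = 0.0129 with an estimated correlation). Markers of Kupffer cells and macrophages moved with them in 18 of 20 members (adjusted p = 4.22e-05, and adjusted p = 0.344 with an estimated correlation), as did neutrophil markers in 12 of 12 (adjusted p = 0.00244, and adjusted p = 0.161 with an estimated correlation). Cholesterol genes moved higher in G62C females than in G62C males in 20 of 21 members (adjusted p = 2.9e-08, and adjusted p = 0.344 with an estimated correlation) and PPAR alpha targets lower in 30 of 33 (adjusted p = 4.42e-07, and adjusted p = 0.344 with an estimated correlation). In R341H, interferon-stimulated genes moved lower in females in 24 of 30 members (adjusted p = 0.000124, and adjusted p = 0.237 with an estimated correlation). Genes of acetaminophen metabolism moved higher in G62C females than in males in 15 of 15 members (median 0.241, adjusted p = 7.05e-08, and adjusted p = 0.0207 with an estimated correlation). Cholesterol genes moved higher in R341H females than in R341H males in 19 of 21 members (median 0.843, adjusted p = 7.59e-15, and adjusted p = 0.237 with an estimated correlation). Across 18193 genes, which are not independent replicates, the female and male differences correlated at r = 0.164 for G62C (permutation p = 0.22) and r = 0.187 for R341H (permutation p = 0.14; r = 0.262 with p = 0.03 without WT female replicate 1).

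The variants were also compared by what they share. Actg1, Rcn2 and Onecut1 fell and Nox4, Cyp4a12a, Ift46 and Zc3h12c rose against WT in both, and Rtp4 fell in G62C by 0.35 and rose in R341H by 0.28. Independent calls would give 0.055 shared rises and 0.02 shared falls among 18193 genes, but both variants were set against the same 8 WT arrays. In 100 simulations of unchanged groups that shared the WT arrays no gene was shared in direction (highest 0), but the median number of calls was 0 for each variant, so these say little about how far the shared arrays bring calls together. Across genes, which are not independent replicates, the differences of the variants correlated at r = 0.264, where simulations of the same kind gave a median of 0.51 and a range of 0.156 to 0.783. With the WT arrays divided so that each variant had its own 4, the median r over 36 divisions was 0.0284, from -0.175 to 0.145.

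The comparison of females with males over all genotypes described the sex bias of these livers. Sult2a2 and Sult3a1, sulfotransferases of female liver, rose by 7.54 ± 0.46 (adjusted p = 4.68e-12) and 6.92 ± 0.60 (adjusted p = 5.03e-09) in females. Cyp2b13 (5.81), Hao2 (5.80), Cyp2b9 (5.51), Cyp3a16 and the transporters Slc22a27, Slc22a26 (4.09) and Slc22a29 (3.57) were also higher, as were Xist (3.98), Cyp3a44 (3.51) and Nt5e (3.36, and -0.037 for 1 of its other probe sets). Cyp4a12a fell by 7.08 ± 0.07 (adjusted p = 1.64e-29), followed by the Y-linked Eif2s3y (-5.48), Cyp2d9 (-5.41), Hsd3b5 (-4.83), Elovl3 (-4.15), Nox4 (-3.70) and the complement gene C6 (-3.65). The Y-linked Uty (-3.21) and Kdm5d (-2.85), Ugt2b38 (-3.01), Scara5 (-2.75) and Omd (-2.21) fell too. With n = 12 arrays per sex 4443 probe sets passed, 2365 higher and 2078 lower in females. The share of higher probe sets depended on scaling: it was 53.2% with the deposited values, 49.4% with new quantile normalization and 60.4% with arrays centred on their medians.

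Of 33 genes listed as female-biased 29 rose and 4 did not pass (list adjusted p = 4.78e-61, and adjusted p = 8.99e-07 with an estimated correlation), and 22 of 26 male-biased genes fell, 1 rose and 3 did not pass (list adjusted p = 5.65e-40, and adjusted p = 1.92e-05 with an estimated correlation). Adjusted over the list alone, 29 female-biased genes rose and 1 fell, and 23 male-biased genes fell and 3 rose. Of 30 interferon-stimulated genes 13 rose in females and 17 did not pass, among the rises Gbp7 (0.83) and Gbp2 (0.61); 20 rose when adjusted over the list alone (list adjusted p = 5.86e-09, and adjusted p = 0.0294 with an estimated correlation). Kupffer cell and macrophage markers were higher in females beside them, with 14 of 20 rising, among them Marco (0.43), Cd68 (0.40) and Clec4f (0.37), and 15 when adjusted over the list alone (list adjusted p = 5.86e-09, and adjusted p = 0.171 with an estimated correlation). Of 29 lipogenesis genes 10 rose, led by the fatty acid translocase gene Cd36 (2.06), and 19 did not pass; 10 rose when adjusted over the list alone (list adjusted p = 8.59e-06, and adjusted p = 0.129 with an estimated correlation). Of 33 PPAR alpha targets 11 rose, among them Acot3 (2.06), Acot4 (1.25) and Vnn1 (2.12), and 22 did not pass; 17 rose when adjusted over the list alone (list adjusted p = 1.61e-08, and adjusted p = 0.347 with an estimated correlation). With the WT arrays alone, 948 probe sets differed between the sexes.

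Tlr8, Tlr7, Prps2, Msl3, Arhgap6 and Hccs are 6 of 7 measured X-linked genes from Tlr8 to Hccs, a set chosen after its values were seen; the seventh, Amelx, differed by 0.06 in R341H males (adjusted p = 0.922). Against WT males, R341H males differed by 0.44, 0.35 and 0.50 for Tlr8, Tlr7 and Prps2, which did not pass (adjusted p = 0.243, 0.356 and 0.0968), and the other 3 rose. The mean of the 6 genes was between 7.28 and 7.45 in the 4 R341H males, between 6.55 and 6.80 in the 8 other males and between 6.64 and 6.90 in the females.

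**Figure D4:**
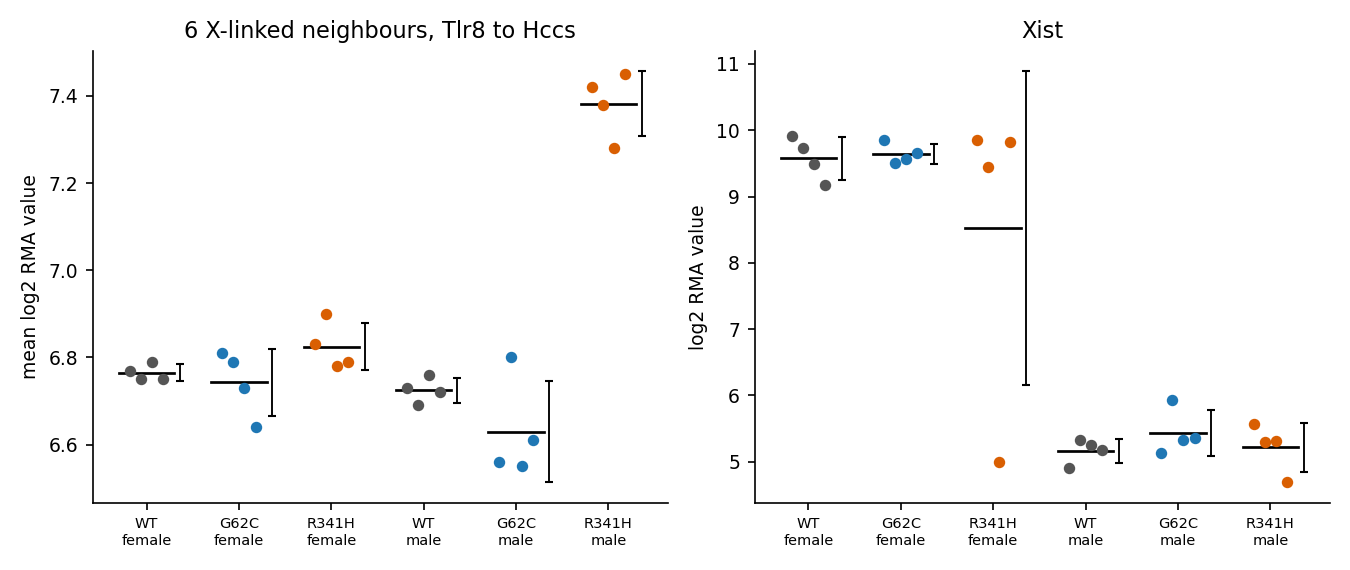
The left panel shows the mean log2 value of Tlr8, Tlr7, Prps2, Msl3, Arhgap6 and Hccs in each of the 24 arrays by group, with a line at each group's mean and a bar for the standard deviation, and the 4 R341H males lie at 7.28 or more while all other arrays lie at 6.90 or less. The right panel shows Xist in the same arrays, with R341H female replicate 3 at 4.99 and the 11 other females at 9.17 or more.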

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

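The tests of the X-linked segment, of chromosome 9, and of a male liver and a failed hybridization behind the array without Xist were chosen only after the result was seen; the test of a single X chromosome was set before its result was seen. Values are log2 units, and the chromosome order of genes is that of assembly GRCm38.p6.

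Of 7 measured X-linked genes from Tlr8 to Hccs, 6 lay above WT in R341H males: Tlr8, Tlr7, Prps2, Msl3, Arhgap6 and Hccs. Of these the last 3 passed, while Amelx, an enamel gene, differed by 0.06. Among 11896 windows of 6 neighbouring bright genes, the window that ranked 1 (mean 0.61) held 5 of the 6 genes. The largest with none of them lay on chromosome 9, from Nxpe2 to Zbtb16 (mean -0.58). A window overlapping it, from Cadm1 to Nnmt, ranked 6 (mean -0.535). Windows on chromosome 7 ranked 3 (Saa3 to Ldha, mean 0.565) and 4 (Sergef to Saa2, mean 0.55). A general shift of X-linked genes is argued against by the median difference of -0.0273 over 313 other X genes, and artefacts of single probe sets by the 3 genes with several bright probe sets, in all 3 of which every one was raised. An extra copy of this segment in R341H males may account for the pattern: all 4 R341H males lay above all 8 other males in the mean of the 6 genes and of all 7, a test on the arrays and genes in which the pattern was found. The Y chromosome of BXSB mice (Yaa) carries such a copy with Tlr7, so a candidate explanation is a Y chromosome of that kind in the R341H breeding line, which no DNA was available to examine. Windows reaching past Tlr8 or Hccs, each with 4 of the 6 genes, had lower means of 0.472 (Tmsb4x to Amelx), 0.461 (Rab9 to Arhgap6) and 0.536 (Prps2 to Erdr1). Those means rest on the raised genes inside. Taking in Tmsb4x for Hccs, or Erdr1 for Tlr8, lowered the mean from 0.61. Taking in Rab9 for Amelx lowered it further, so Rab9 lay below the 0.06 of Amelx. The windows thus gave no sign of a rise in the nearest bright genes on either side, though these genes were not tested singly. Interferon-stimulated genes were higher in the same males (median 0.247), and whether the segment or the K8 variant is the origin of that difference was not tested.

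R341H female replicate 3 had a Xist value of 4.99, where 11 other females had 9.17 to 9.91. A male liver under a female name is argued against by its Eif2s3y value of 3.27, far below the males' 7.99 to 8.56, and a failed hybridization by its median correlation of 0.9954 with its group, within the 0.9934 to 0.9964 of the other arrays. A single X chromosome in this animal may account for it: the mean of 4 X-linked genes (Kdm6a, Kdm5c, Eif2s3x and Ddx3x) was 8.589, below the 8.72 to 9.075 of all 11 other females and within the males' 8.331 to 8.756. The margin was small, Ddx3x at 11.19 lay within the female range of 11.10 to 11.75, and loss of Xist expression without loss of an X stays open. G62C male replicate 2 had the highest Xist value of the males, 5.93 against at most 5.57 in the other 11, and 5.41 against at most 3.89 at another probe set; a share of female tissue in this sample was not tested and stays open.

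Of the 21 genes that differed from WT in G62C, 8 were on chromosome 9 (38.1%, against 5.56% of all genes; exact one-sided hypergeometric test, p = 9.4e-06 for this chromosome, chosen after it was seen), and chance placement is argued against, since a share of 5e-04 of 10000 random gene sets held as many genes of any 1 chromosome. A chromosome 9 difference particular to the WT mice, as the sole origin, is argued against for the 3 genes that also differed between the variants, Sc5d, Treh and Nxpe2 (adjusted p = 0.00636, 0.00214 and 0.0295). For the other 5 it stays open: Ift46, Zc3h12c, Rcn2 and Onecut1, the 4 of 8 that differed from WT in the same direction in R341H by at least 0.5 of the G62C difference, and Fam219b, at -0.135 in R341H and -0.274 in G62C. Sequence differences under single probe sets could not be told apart from changes in transcript amount: 0 of the 2 genes with other bright probe sets, Sc5d and Onecut1, had them moving by at least 0.5 of its own difference, and 2 genes are too few. In R341H, 12 of 133 called genes were on chromosome 9 (9.02%, exact one-sided hypergeometric p = 0.0666). In R341H males, overlapping chromosome 9 windows from Nxpe2 to Zbtb16 and from Cadm1 to Nnmt had means of -0.58 and -0.535. Both hold Nnmt, which lay at 7.232 to 9.203 in R341H males against 10.15 to 10.64 in WT males. The 2 means therefore rest largely on this gene and are not separate observations. Founder DNA on chromosome 9 that differs between the lines was not tested and stays open for both variants, as does the K8 variant itself.

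The test of the difference between sexes in the effect of a variant called 8 named genes. Cyp4a12a, the 1 call for G62C, had a difference 1.24 higher in females, but 8 of 100 splits of the arrays gave as many calls, so chance cannot be excluded, and the call was lost when each of 5 of the 24 arrays was left out. In R341H, the female difference minus the male one was -2.03 for Cyp17a1, -0.83 for Hccs, -0.98 for Msl3, -2.42 for Cyp3a44, 1.20 for Tmem14a, 0.71 for Tmem107 and 1.89 for Nox4. Nox4 averaged 4.66 in WT females and 9.54 in WT males.

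For 163 of the genes named in the text, 745 combinations of a gene and a group of 4 arrays were examined for 1 array far from the other 3, by the gap to its nearest neighbour as a share of the group's range. Chance flags about 1 in 20 such groups, or 37.2 of them, and 32 were found. G62C female replicate 1 was low for Ccn2 (0.898) and high for Hnf4a (0.84). R341H female replicate 2 was low for Ccn2 (0.875). R341H female replicate 4 was low for Rtn4 (0.906) and high for Cd3g (0.834) and Igtp (0.834). R341H male replicate 1 was high for Cd5l (0.964). G62C female replicate 4 was low for Cd74 (0.872). WT female replicate 1 was low for Cyp2b13 (0.878) and Eif2s3y (0.853). G62C male replicate 2 was high for Cyp3a16 (0.842), Nxpe2 (0.837) and Tanc2 (0.925). R341H female replicate 3 was low for Cyp3a16 (0.886), Nnmt (0.903) and Xist (0.917). WT female replicate 2 was high for Cyp7a1 (0.83) and Hao2 (0.865). R341H male replicate 4 was low for Fcgr2b (0.894) and high for Nox4 (0.837). WT female replicate 4 was low for Rab8b (0.924) and high for Gdpd1 (0.832). G62C male replicate 1 was low for H2-DMa (0.888) and high for Hspa1a (0.954). G62C female replicate 2 was high for Igfbp1 (0.9). G62C male replicate 4 was high for Krt8 (0.855). R341H male replicate 3 was low for Onecut1 (0.847). G62C female replicate 3 was high for Psmb8 (0.842). WT male replicate 2 was high for Syt11 (0.885) and Tmem107 (0.83). WT male replicate 4 was low for Treh (0.871). G62C male replicate 3 was high for Uty (0.949). The number in brackets is that share.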

How the results depend on the processing

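Fits without R341H female replicate 3 and G62C male replicate 2, and counts without genes of chromosomes 9 and X, were chosen only after the result was seen. Counts are probe sets past the threshold, with all arrays and probe sets 39 for G62C, 248 for R341H and 1045 for G62C against R341H, 92 and 9 for G62C in females and males, 295 and 31 for R341H in females and males, 1 and 11 for the interactions of G62C and R341H with sex, and 4443 for females against males. Limits are set by 4 arrays per group and by signal over background, for which the brightness filter at 5.07 was the test. Among 23357 alternative values of named genes 21663 kept direction and side of the threshold, 1427 no longer passed, 224 newly passed and 6 changed sign with no call on either side. The remaining 37, all of them other probe sets of the same gene, turned direction where at least 1 of the values compared had passed. Among 3538 alternative values of lists, 3106 kept both, 431 no longer passed and 1 turned. That list, Kupffer cell and macrophage markers in G62C males, was higher without G62C male replicate 1 (adjusted p = 1), while it was lower without R341H female replicate 3 and G62C male replicate 2 (adjusted p = 0.00139). A bright other probe set of Hnf4a passed in the opposite direction for females against males, 0.21 (adjusted p = 0.0317) against -0.24. The cause was not tested for either.

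By construction fewer probe sets are tested with 1 per gene, which gave 23 for G62C, 15 for R341H males, 7 for the R341H interaction and 2522 for the sexes. Leaving out genes of chromosomes 9 and X also removes tests, and gave 23 for G62C, 1 for G62C males and 13 for R341H males. Other counts fell less in proportion, to 278 in R341H females, 71 in G62C females, 198 for R341H and 974 between the variants. Much of the male and G62C counts thus rested on genes of these chromosomes. A threshold of 1.5-fold, which by construction removes calls, left 13 for G62C, 33 for R341H, 166 between the variants, 48 in G62C females, 130 in R341H females and 404 between the sexes. Fits to the compared groups, with fewer arrays to estimate variances, gave 24 for G62C, 23 in G62C females, 145 in R341H females, 8 in R341H males and 0 for the G62C interaction in limma, the only tool run (2880 had an unadjusted p under 0.05 in the fit to all arrays); WT arrays alone gave 948 between the sexes. The cause was not tested for the following: 432 for R341H and 3 in G62C males with probe sets above the median brightness, 4 in G62C males with new quantile normalization, 50 in G62C females and 4 in G62C males with median centring, 5 in G62C males with an intensity trend and robust variances, 140 in G62C females with array weights, and 12 for G62C in an additive model. Without R341H female replicate 3 and G62C male replicate 2 the counts were 152 for R341H and 87 in R341H females, of which 141 and 79 were among the probe sets called with all arrays.

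Other probe sets of named genes lay on the opposite side of 0 in 36 of 285 cases without passing, 29 of them with a mean at or under the median brightness of 5.07; the cause was not tested. Their log2 differences were as follows, for G62C Tanc2 -0.010, Rcn2 0.021; for R341H Rcn2 0.072, Inca1 0.051, Syt11 0.0055 and 0.015, Pole4 0.00094, Bcl2l11 0.028; between the variants Fdft1 0.085, Acacb -0.040, Plk2 0.063, Rtn4 0.031, Ntrk2 0.013, 0.0031, 0.013, 0.065 and 0.032. Within the sexes these were, in G62C females Rtp4 0.090; in G62C males Rcn2 0.063; in R341H females Fdps -0.062, Fdft1 -0.092 and -0.0064, Plk2 -0.070; in R341H males Tsc22d1 -0.0065, Rtn4 -0.071 and -0.064, Rcn2 0.058, Inca1 0.11. Elsewhere these were, for the R341H interaction Tmem107 -0.024; between the sexes Nt5e -0.037, Acacb -0.086, Psmd11 0.037, Fcgr2b -0.100, Add2 0.015, 0.012 and 0.028.

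The replicate numbers do not pair the samples: of 60 pairs of arrays with the same number 9 correlated above 0.1 (median r = 0.0108, against -0.00782 for 180 other pairs), and 3 of 24 arrays were closest to one of their own number. With the number as a block the G62C interaction count was 2, and with it as a random block 44 in G62C females and 4 in G62C males; the cause was not tested.

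With each array left out in turn, counts ranged from 9 (WT male replicate 2) to 63 (WT female replicate 1) for G62C, 121 (WT male replicate 2) to 371 (WT female replicate 2) for R341H, 675 (G62C male replicate 1) to 1189 (R341H male replicate 4) between the variants, 37 (G62C female replicate 3) to 109 (G62C male replicate 2) in G62C females, and 0 (G62C male replicate 1) to 12 (WT female replicate 1) in G62C males. They ranged from 32 (WT female replicate 3) to 537 (WT female replicate 2) in R341H females, 6 (WT male replicate 1) to 41 (G62C male replicate 1) in R341H males, 0 (G62C male replicate 3) to 4 (G62C female replicate 4) for the G62C interaction, 4 (R341H female replicate 1) to 19 (WT female replicate 2) for the R341H interaction, and 3905 (G62C female replicate 3) to 4610 (WT female replicate 4) between the sexes. Of the 24 arrays, 9, 4, 2, 11, 14, 6, 4, 15, 10 and 0 moved these counts, in this order, by over 1.5 times. Correlations across genes, which are not independent replicates, ranged from 0.0577 to 0.277 for G62C between sexes, 0.0898 to 0.262 for R341H between sexes (highest, with p = 0.03, without WT female replicate 1) and 0.189 to 0.343 between the variants.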

Other observations

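No test here was chosen only after the result was seen. In G62C against R341H, the lists of lipid synthesis, cell death, inflammation and heat shock genes passed with the preset correlation and none of these 4 with an estimated one. Of 29 lipogenesis genes 5 fell and 1 rose in G62C against R341H, and 23 did not pass (list adjusted p = 0.00745, and adjusted p = 0.291 with an estimated correlation); adjusted over the list alone, 7 fell and 3 rose. Acacb, which makes malonyl-CoA at mitochondria, rose by 0.55 ± 0.11 (adjusted p = 0.00494, higher in 8 of 8 arrays; another probe set gave -0.040 and did not pass), and Dgat2, an enzyme of triglyceride synthesis, fell by 0.27 ± 0.06 (adjusted p = 0.00989, lower in 7 of 8 arrays). In the cell death list 17 of 22 genes were lower in G62C than in R341H, and Bid, which links death receptors to mitochondria, fell by 0.41 ± 0.07 (adjusted p = 0.00119). That list had an adjusted p of 0.00997, and adjusted p = 0.111 with an estimated correlation; 21 members did not pass, and 3 fell and 1 rose when adjusted over the list alone. Of 21 NF-kB and inflammatory genes 15 were lower (list adjusted p = 0.0161, and adjusted p = 0.11 with an estimated correlation), and the interferon-induced chemokine gene Cxcl9 fell by 0.77 ± 0.19 (adjusted p = 0.0237); 2 fell when adjusted over the list alone. Of 15 heat shock and keratin aggregate proteins 12 were higher (list adjusted p = 8.76e-05, and adjusted p = 0.183 with an estimated correlation), and the small heat shock protein gene Hspb1 rose by 0.41 ± 0.08 (adjusted p = 0.00636); 4 rose when adjusted over the list alone. The 30 genes of bile acid synthesis and transport did not pass as a list (adjusted p = 0.251): 4 rose, among them Acox2 (0.46), Cyp39a1 (0.68) and the phospholipid exporter gene Abcb4 (0.29), Cyp7a1 fell and 25 did not pass, with 5 rising and 2 falling when adjusted over the list alone.

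Acute phase genes lay on opposite sides of WT in the sexes of R341H. They were above WT in 24 of 27 members in males (adjusted p = 0.000137, and adjusted p = 0.557 with an estimated correlation) and below WT in 20 of 27 in females (adjusted p = 0.000616, and adjusted p = 0.411 with an estimated correlation). None of the 27 passed over all genes in males and 4 rose when adjusted over the list alone; in females 1 fell, and 3 when adjusted over the list alone. Saa2, a serum amyloid gene, had a difference of 1.28 ± 0.38 in males (adjusted p = 0.331), and Lcn2 fell by 2.07 ± 0.47 in females (adjusted p = 0.0392). The test of the difference itself had 23 of 27 members lower in females (adjusted p = 3.36e-09, and adjusted p = 0.237 with an estimated correlation), with 3 lower when adjusted over the list alone. The same test in G62C had 23 of 27 members lower in females (adjusted p = 2.33e-06, and adjusted p = 0.232 with an estimated correlation), with 1 lower when adjusted over the list alone. In G62C females the metallothionein gene Mt2 fell by 1.04 ± 0.19 (adjusted p = 0.014).

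Each count was set against other splits of the same arrays, the real one included in the number of splits. Of 100 splits, 1 gave a count as large as the real 39 for G62C against WT (highest other 7), 1 as large as 248 for R341H against WT (highest other 42), 1 as large as 1045 for G62C against R341H (highest other 155) and 1 as large as 4443 for females against males (highest other 452). In each case that 1 was the real split, which argues against chance for these. Of 35 splits, 1 gave a count as large as 92 in G62C females (highest other 3), 9 in G62C males (highest other 1), 295 in R341H females (highest other 1) and 31 in R341H males (highest other 8). That 1 was the real split, and 1 of 35 is the smallest share possible here. Such a share argues against chance without excluding it. None of these shares was adjusted for the number of counts tested. For the interaction of R341H with sex 2 of 100 splits gave a count as large as 11, a share under 0.05. The highest other count was 13, above the real one, so chance is not excluded. For the interaction of G62C with sex 8 of 100 splits gave a count as large as 1 (highest other 6), so chance cannot be excluded.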
